A study of Mus musculus with 21 samples.

How the data were processed

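The series holds 21 Affymetrix mouse arrays of total RNA from the mouse dentate gyrus, 3 in each of 7 groups named from the labels. The values are the deposited intensity of each probe set, linear and scaled by the authors so that the mean of each array after leaving out the lowest and highest 2% of probe sets is 150. The processing tool is not given in the sources used here, and no detection calls were used. The samples were grouped, the comparisons, tests, gene lists, alternatives and rules for naming genes were chosen before the data were examined, and anything chosen later is said to be so.

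Of 45101 probe sets, 34945 had 1 gene symbol, 932 several and 9160 none, and 64 controls were left out. Of those with 1 symbol, 34741 matched the reference gene table by Entrez ID. That table served for names and neighbouring genes, and no coordinates are printed. Values were transformed as log2(value + 16). Array medians then ran from 5.19 to 5.49, a spread of 0.30 above the limit of 0.25 set beforehand, so quantile normalization was applied. The upper 60% of probe sets by mean (27022, mean log2 of 4.90 or more) were kept, and each gene was read from its probe set of highest mean, which gave 12499 genes. Intensities are given as deposited, and log2 differences are from normalized values.

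One limma fit (limma 3.58.1 in R 4.3.3, with the data.table package at version 1.17.8) had a coefficient per group over all 21 arrays, with 14 residual degrees of freedom, and moderated variances with a trend on mean level. Tests were two-sided and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Errors on log2 differences are standard errors from this fit, and errors on intensities are SDs. The comparisons were the 3 pairs of groups in set 1, bitransgenic against monotransgenic in experiment 2 and in set 3, the mean of the 3 within-set differences with the transgene on, and the 3 differences between those differences. *Rtn4r* was also tested by exact permutation of normalized log2 values, with 20 labelings of 3 against 3 and 8000 within the 3 sets. Correlations of log2 differences between sets were set against 400 relabelings of the arrays within sets. On simulated data with 50 genes changed at each size, the fit recovered 52% to 62% of changes of 1 log2 unit and 86% to 98% of changes of 1.5 in the comparisons of 3 against 3 tested, and 94% and 100% over the 3 sets. The simulation drew genes independently, with the same spread in all arrays, and changed the same genes in all 3 sets. These shares need not hold for the real arrays, which varied more in experiment 2. *Rtn4r*, at 2.47 log2 units, did not pass in set 3.

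There were 31 gene lists, of which 30 had the 3 measured members needed for a test. They covered NgR receptors, co-receptors and ligands; genes of the chromosome 12 segment near *Vipr2*; immediate early genes; synaptic and plasticity genes; axon growth and regeneration genes; dentate granule cell, CA1, and CA3, CA2 and hilar mossy cell markers. They also covered neurogenesis and proliferation, inhibitory neuron, thalamus, neocortex and striatum, choroid plexus, oligodendrocyte and myelin, astrocyte, microglia, endothelial and pericyte, meningeal and fibroblast, blood cell and sex-linked markers. The rest were reactive astrocyte, activated microglia, interferon response, antigen presentation, p53 and DNA damage, ATF4 and unfolded protein response, heat shock, oxidative phosphorylation, glucocorticoid response and circadian clock genes. The result of 1 further list is not reported here. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of each comparison, with camera at an estimated correlation and fry beside it. Counts of members are given over all genes and adjusted over the list alone.

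Genes were named by rule: *Rtn4r* always, then for each of the first 6 comparisons up to 12 largest rises and 12 largest falls among genes that passed without overlap of the groups (over the 3 sets, with the same sign in each), filled to 10 by lowest p. Up to 4 members of lowest p were named per list and 5 genes per difference between sets. *Tox3* over the 3 sets, genes traced across comparisons, *Xist* and *Eif2s3y* were named after their values were seen. Alternatives tried were pseudocounts of 1 and 64, no filter, the upper 40% of probe sets, the deposited scale, centring on the 75th percentile, fits within sets, all probe sets, the mean of a gene's probe sets, array weights, no variance trend, a Gapdh 3' to 5' or *Xist* covariate, title prefix as a factor in set 3, leaving out set 3, a threshold of 0.1 and leaving out each array. Added after seeing the data were the removal of the 2 arrays of highest actin ratio, of experiment 2, and of *Rtn4r* from its own list. Figures were drawn with matplotlib.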

Results

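Gene expression was measured in the dentate gyrus of the hippocampus of mice built to overexpress the Nogo receptor NgR (gene *Rtn4r*) from a transgene that the transactivator tTA switches on and doxycycline keeps off. The series held 21 arrays in 7 groups of 3. Set 1 compared bitransgenic mice after doxycycline removal, bitransgenic mice kept on a doxycycline diet, and monotransgenic mice without tTA. Experiment 2 compared bitransgenic mice never given doxycycline with monotransgenic mice on water, and set 3 compared bitransgenic with monotransgenic mice whose treatment the labels do not give. Groups of 3 limit the precision of every comparison. Beyond sample numbers, nothing in the labels says that the samples came from separate animals, so the p-values measure the spread between these samples. In limma that spread was pooled over all 7 groups.

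*Rtn4r*, which codes for a receptor of myelin proteins that restrain axon growth, was high in every group in which the transgene was meant to be on. Its mean intensity was 684 ± 681 (SD, n = 3) after doxycycline removal, 90.4 ± 19.3 on the doxycycline diet and 80.4 ± 17.4 in the monotransgenic mice of set 1. It was 574 ± 196 against 141 ± 39.0 in experiment 2 and 663 ± 96.6 against 110 ± 23.7 in set 3 (n = 3 each). The 9 transgene-expressing arrays ranged from 254 to 1469 and the 9 monotransgenic arrays from 63.8 to 185, so no array crossed over. Over the 3 sets *Rtn4r* rose by 2.28 ± 0.23 log2 units (standard error), 4.86-fold (limma adjusted p = 2.46e-05; exact permutation p = 0.00025 of 8000 relabelings within sets). The other receptors, co-receptors and ligands of the pathway did not follow it. Of 10 list members measured, *Rtn4r* alone rose over all genes and adjusted over the list alone, 9 did not pass, and *Rtn4rl2* (0.14), *Ptprs* (−0.23) and *Tnfrsf19* (0.14) had the next lowest p. Within set 1 a single array after doxycycline removal stood at 1469 and the others at 329 and 254. Each comparison of 3 against 3 with the transgene on gave an exact p of 0.1, the smallest possible.

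**Figure D1:**
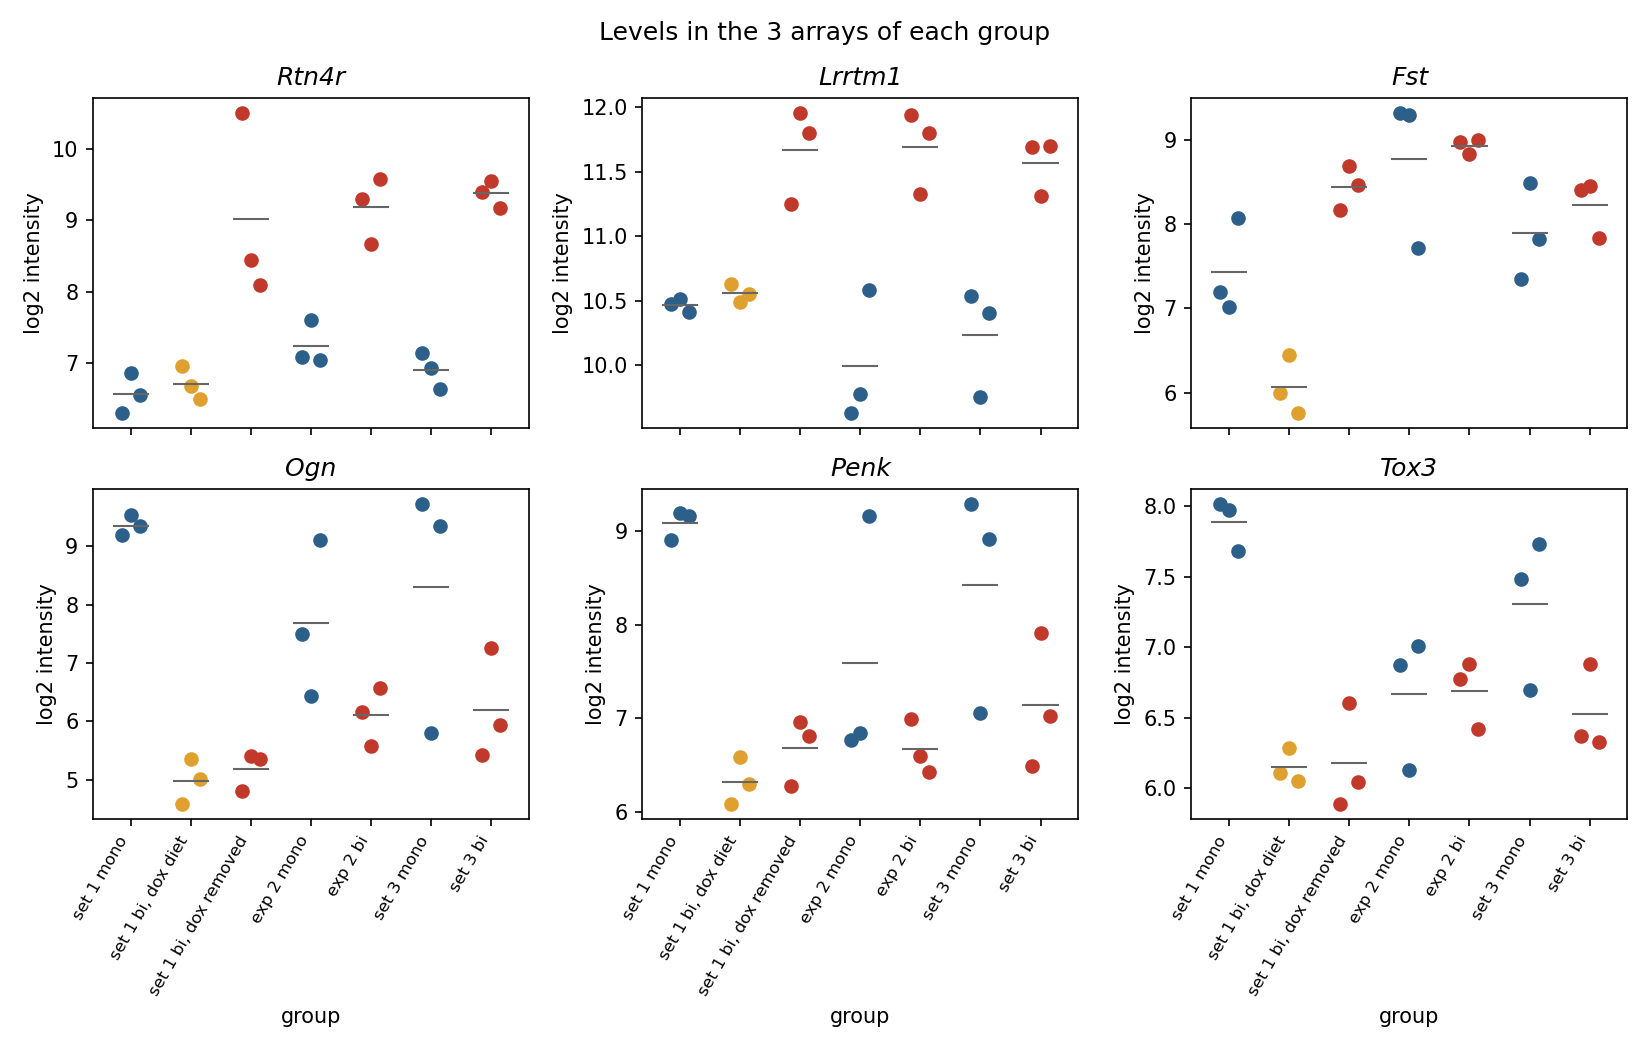
Normalized log2 intensity (vertical axis) of 6 genes in each array of the 7 groups (horizontal axis), with a line at the group mean. *Rtn4r* and *Lrrtm1* were higher in the 9 transgene-expressing arrays (red) than in the other 12, while *Ogn*, *Penk* and *Tox3* varied among the monotransgenic arrays (blue).

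Removal of doxycycline within the bitransgenic mice of set 1 raised 4 genes and lowered none. *Fst* rose by 2.37 ± 0.36 log2 units (5.18-fold, adjusted p = 0.0199) and *Pmepa1* by 1.30 ± 0.20 (adjusted p = 0.0199); follistatin binds and blocks activins, and Pmepa1 is a feedback inhibitor of TGF-beta signalling. *Rtn4r* rose by 2.30 ± 0.40 (adjusted p = 0.0405) and *Fam107b*, a relative of an actin-binding protein, by 1.20 ± 0.20 (adjusted p = 0.0343). Of 14 settings *Fst*, *Pmepa1*, *Rtn4r* and *Fam107b* passed in 14, 12, 8 and 11, and of 6 fits without 1 array in 0, 2, 1 and 0. Without removed replicate 1 the rise of *Rtn4r* was 1.55. Among the genes that did not pass, *Inhba*, which codes for the activin A subunit, stood 2.08 log2 units higher (adjusted p = 0.0708), *Colgalt2* 1.63 higher (0.065), *Trib2* 1.20 higher, and *Popdc3* (−1.25), *Septin6* (−1.16) and *Parm1* (−0.67) lower. Immediate early genes, which neurons switch on with activity, shifted upward as a list: 16 of 22 members were higher, led by *Npas4* (0.86), *Fos* (1.18), *Dusp1* (0.68) and *Egr1* (0.39), with none past the threshold over all genes and 1 that rose adjusted over the list alone (camera adjusted p = 0.0396). With an estimated correlation its adjusted p was 0.512. Its mean per array was 0.092, 0.229 and −0.285 after removal and −0.186, −0.279 and −0.131 on the diet, so replicate 3 after removal lay under every diet array. Against monotransgenic mice 11 members were higher and 11 lower (median −0.02, camera adjusted p = 0.984). The call was lost without removed replicate 1 or 2 or diet replicate 1 or 2, at adjusted p of 0.0655, 0.47, 0.131 and 0.291. Axon growth and regeneration genes shifted upward too, with 10 of 14 members higher, led by the growth cone protein gene *Marcks* (0.49) and *Stmn1* (0.18), none past the threshold over all genes and 1 that rose adjusted over the list alone (camera adjusted p = 0.0396; adjusted p = 0.194 with an estimated correlation). Its mean per array was 0.129, 0.182 and 0.069 after removal and 0.027, −0.153 and 0.06 on the diet. Without diet replicate 2 its median went from 0.16 to 0.07 (camera adjusted p = 0.291), and the call was lost without removed replicate 2 as well (0.215). Heat shock genes had 10 of 13 members higher, *Hsph1* (0.24) and *Hspa8* (0.10) foremost, with 0 past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.0466; adjusted p = 0.512 with an estimated correlation). This call was lost without removed replicate 1 or 2 or diet replicate 1 or 2, and without diet replicate 1 the median went from 0.12 to 0.08. The count of 4 came from limma over 12499 genes, of which 630 had an unadjusted p under 0.05 against 625 by chance. Groups did not overlap in 16.2% of genes, against 10% by chance. Fitted on the arrays of set 1 alone the count was 85 (44 up, 41 down), with array weights it was 68 (41 up, 27 down), without removed replicate 1 or 2 or diet replicate 1 or 2 it was 0, and without diet replicate 3 it was 1.

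Bitransgenic mice after doxycycline removal differed in 9 genes, 2 up and 7 down, from the monotransgenic mice without tTA, which were off doxycycline too. *Rtn4r* rose by 2.44 ± 0.40 log2 units and *Klf10*, a transcription factor induced by TGF-beta, by 1.35 ± 0.23 (adjusted p = 0.032 for both). *Ogn* fell by 4.16 ± 0.74 (adjusted p = 0.0321) and *Lum* by 1.48 ± 0.28 (adjusted p = 0.0468); both code for small matrix proteoglycans found in the meninges. *Igfbp5* (−2.43 ± 0.46), *Upk1b* (−2.35 ± 0.41), *Tox3* (−1.71 ± 0.26), the potassium channel subunit gene *Dpp10* (−1.01 ± 0.19) and the kinase gene *Bcr* (−0.85 ± 0.15) fell too, with adjusted p from 0.032 to 0.0468. *Fam107b* stood 1.05 higher without passing (adjusted p = 0.0536). Markers of dentate granule cells, the main neurons of this region, shifted downward: 12 of 16 were lower, none past the threshold over all genes, and 6 fell adjusted over the list alone, among them *Glis3* (−1.10), *Calb1* (−0.48), *C1ql3* (−0.54) and *C1ql2* (−1.80) (camera adjusted p = 0.00525; adjusted p = 0.285 with an estimated correlation). Their median of −0.20 was −0.15 without removed replicate 1, which lost the call (camera adjusted p = 0.0525), and −0.32 without removed replicate 2. Of 6 meningeal and fibroblast markers 4 were lower, and *Ogn* and *Lum* fell both over all genes and adjusted over the list alone (camera adjusted p = 0.0174; adjusted p = 0.285 with an estimated correlation). Without monotransgenic replicate 1 the median of that list went from −0.45 to −0.16 and the call was lost (camera adjusted p = 0.147). All 4 measured genes of a chromosome 12 segment around *Vipr2* were lower, *Ptprn2* most (−0.59), with 0 past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.0355; adjusted p = 0.285 with an estimated correlation). That call was lost without removed replicate 2 or 3 or monotransgenic replicate 2, at adjusted p of 0.0809, 0.0542 and 0.13. In limma 982 genes had an unadjusted p under 0.05, and 22.3% of genes had groups that did not overlap, against 10% by chance. Fitted on set 1 alone the count was 330 (147 up, 183 down), without monotransgenic replicate 1 or 2 it was 0, without removed replicate 1 or 3 it was 1, and without removed replicate 2 it was 4.

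With the transgene held off by doxycycline, the bitransgenic mice still differed from the monotransgenic mice in 3 genes. *Ogn* fell by 4.37 ± 0.74 log2 units (adjusted p = 0.038) and *Tox3*, a transcription factor gene, fell by 1.74 ± 0.26 (adjusted p = 0.0265), while the septin gene *Septin6* rose by 1.34 ± 0.23 (adjusted p = 0.038). *Rtn4r* itself differed by 0.14 ± 0.40 (adjusted p = 1; exact p = 0.5). Genes that did not pass included *Glis3* (−1.32, adjusted p = 0.0801), the enkephalin precursor gene *Penk* (−2.76, adjusted p = 0.116), *Nfatc2* (0.92), *Lypd1* (−0.92), *Bhlhe40* (−0.77), *Ric8a* (−0.75) and the dopamine transporter gene *Slc6a3* (−1.11). The *Vipr2* segment shifted downward as a list, with a median of −0.66 and none of 4 past the threshold over all genes. *Ptprn2* (−0.98), *Esyt2* (−0.68), *Ncapg2* (−0.64) and *Wdr60* (−0.59) all fell adjusted over the list alone (camera adjusted p = 1.95e-06; adjusted p = 0.0117 with an estimated correlation; fry adjusted p = 0.0161). It was the single call among 16 over the 6 comparisons that held with an estimated correlation or in fry. Dentate granule cell markers were lower in 12 of 16 members, with *Glis3* the 1 that fell adjusted over the list alone and 0 over all genes (camera adjusted p = 0.00152; adjusted p = 0.354 with an estimated correlation). Immediate early genes were lower in 18 of 22 members, led by *Jun* (−0.53), *Fosl2* (−0.88) and *Npas4* (−0.71), with 0 past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.0105; adjusted p = 0.354 with an estimated correlation). Their mean per array was −0.186, −0.279 and −0.131 on the diet and −0.013, −0.15 and 0.257 in monotransgenic mice, so monotransgenic replicate 2 lay under diet replicate 3. Their median of −0.15 was −0.06 without monotransgenic replicate 3 (camera adjusted p = 0.375), and −0.24 without monotransgenic replicate 2 or diet replicate 3. The call was also lost without diet replicate 1 (0.0764) or 2 (0.0713). Oligodendrocyte and myelin markers were lower in 13 of 17, *Ermn* most (−1.37), again with 0 past the threshold on either count (camera adjusted p = 0.03; adjusted p = 0.408 with an estimated correlation). Their mean per array was −0.229, −0.287 and 0.293 on the diet and 0.212, 0.082 and 0.132 in monotransgenic mice, so diet replicate 3 lay above every monotransgenic array. Their median of −0.21 was −0.38 without that array and −0.06, −0.13 and −0.17 without diet replicate 2, monotransgenic replicate 1 and diet replicate 1, each of which lost the call (camera adjusted p of 0.465, 0.244 and 0.34). In limma 481 genes had an unadjusted p under 0.05 against 625 by chance, while 14.9% of genes had groups that did not overlap, against 10% by chance. The count of 3 became 0 without any 1 of the 6 arrays.

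In mice never given doxycycline, 12 genes passed in experiment 2, 2 up and 10 down. *Lrrtm1*, which codes for a leucine-rich synapse-organizing protein of excitatory synapses, rose by 1.69 ± 0.23 log2 units (adjusted p = 0.00639), and *Pgap1*, which remodels the lipid anchors of membrane proteins, by 1.16 ± 0.22 (adjusted p = 0.0499). *Gtpbp6* fell by 1.63 ± 0.25 (adjusted p = 0.0122), the carbonic anhydrase gene *Car3* by 1.53 ± 0.27, the vesicle tethering gene *Trappc3* by 1.37 ± 0.26 and *Ubash3a* by 1.22 ± 0.22. The bitransgenic means of *Gtpbp6* (log2 4.65), *Car3* (4.24) and *Ubash3a* (4.595) lay under the filter limit of 4.90, so the sizes of these falls are uncertain. Over the settings and fits without 1 array they ran from −2.65 to −0.79, −3.58 to −0.65 and −2.42 to −0.52. *Trappc3* stood at log2 9.05, 7.43 and 8.91 in the bitransgenic arrays, and without replicate 2, the array of highest actin 3' to 5' ratio, it fell by 0.86. *4930432L08Rik*, *Fbxl15*, *Habp2*, *Ceacam1*, *Zc3h18* and the splicing factor gene *U2af1* fell by 0.82 to 1.18 log2 units, with adjusted p from 0.0342 to 0.0499. The bitransgenic means of *Fbxl15* (log2 4.43) and *Habp2* (4.495) lay under the filter limit too. Their differences ran from −2.25 to −0.46 and from −2.15 to −0.45 over the same settings and fits. *Rtn4r* stood 1.93 ± 0.40 higher without passing over all genes (adjusted p = 0.062). Oligodendrocyte and myelin markers shifted downward: 14 of 17 were lower, none past the threshold over all genes, and *Olig1* (−0.70) and *Pdgfra* (−0.89) fell adjusted over the list alone, with *Mobp* at −0.53 (camera adjusted p = 0.0261; adjusted p = 0.776 with an estimated correlation). Without bitransgenic replicate 2 the median of the list went from −0.35 to −0.16 and the call was lost (camera adjusted p = 0.115). It was lost too without bitransgenic replicate 1 (0.32) or monotransgenic replicate 1 (0.422) or 2 (0.0648). RNA quality varied most here. The 3' to 5' log2 ratio of the beta-actin control ran from 4.84 to 6.45, against 4.17 to 5.12 in the other 2 sets, and the 6 arrays held 53.3% of the residual variance of all 21. The median SD of a gene was 0.28 in the monotransgenic and 0.30 in the bitransgenic arrays, against 0.14 to 0.16 in the groups of the other sets. The fit gave all groups 1 spread per gene, so its standard errors and p-values tend to understate the spread of experiment 2. *Xist*, the X-inactivation RNA of female cells, had intensities of 2361 to 4750 in experiment 2 and 9.59 to 33.7 in the other sets. The Y-linked *Eif2s3y* had 0.316 to 9.84 against 395 to 680. These are levels of female samples in experiment 2 and of male samples in the other sets, though the labels give no sex. In limma 1806 genes had an unadjusted p under 0.05, yet 8.69% of genes had groups that did not overlap, against 10% by chance. Without the 2 arrays of highest actin ratio, an alternative chosen after seeing the data, the count was 518 (211 up, 307 down) with all 12 genes kept, and on the arrays of experiment 2 alone it was 0. Without single arrays it was 646 and 7 (monotransgenic replicates 1 and 3) and 357, 46 and 5 (bitransgenic replicates 1, 2 and 3). *Lrrtm1* and *Gtpbp6* passed without each of 6 arrays, and the other 10 genes in 2 to 5 of these 6 fits.

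No gene passed in set 3. *Rtn4r* stood 2.47 ± 0.40 log2 units higher in the bitransgenic mice (limma adjusted p = 0.0616) and *Lrrtm1* 1.34 ± 0.23 higher (adjusted p = 0.0837). The next lowest p belonged to *Bcat1*, a branched-chain aminotransferase gene (1.13, adjusted p = 0.9), the autophagy gene *Fyco1* (−0.70), *Tex15* (1.91), *Ccdc80* (1.61), *Gpr62* (0.68), *A230006K03Rik* (−0.85), the adhesion gene *Cntnap5a* (−1.04) and *A230051N06Rik* (0.61). Dentate granule cell markers shifted downward, with 12 of 16 lower, among them *Rfx3* (−0.55), *Prox1* (−0.57) and *C1ql3* (−0.40), *Il16* higher (0.70), and 0 past the threshold over all genes or adjusted over the list alone (camera adjusted p = 0.023; adjusted p = 0.561 with an estimated correlation). The call was lost without monotransgenic replicate 1 (0.218) or 3 (0.147) or bitransgenic replicate 1 (0.221). The count of 0 came from limma with 524 genes at an unadjusted p under 0.05, fewer than the 625 expected by chance, while 13.5% of genes had groups that did not overlap, against 10% by chance. Without monotransgenic replicate 2 the count was 73 (39 up, 34 down).

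Over the 3 sets together, bitransgenic mice with the transgene on differed from their monotransgenic mice in 9 genes, 3 up and 6 down, of which 8 had the same sign in every set. *Lrrtm1* rose by 1.41 ± 0.13 log2 units (2.66-fold, adjusted p = 1.82e-05), at 1.20, 1.69 and 1.34 in set 1, experiment 2 and set 3. Its rise was 1.51 in experiment 2 without monotransgenic replicate 1, and 1.10 in set 3 without monotransgenic replicate 2. *Lrrtm1* was low in both of these arrays. *Zdhhc22*, which codes for a palmitoyltransferase, rose by 1.18 ± 0.20 (adjusted p = 0.0272). Its log2 level was 8.21 and 8.54 in monotransgenic replicates 1 and 2 of experiment 2 and 8.13 in monotransgenic replicate 2 of set 3. The other monotransgenic arrays stood at 6.64 to 7.91 and the transgene-expressing arrays at 8.5 to 9.195. *Ogn* fell by 2.61 ± 0.42 (adjusted p = 0.0164), *Igfbp5* by 1.48 ± 0.26 (adjusted p = 0.0352), *Tcerg1l* by 0.88 ± 0.16 (adjusted p = 0.0356), *Bcr* by 0.59 ± 0.09 (adjusted p = 0.00408) and *Zcchc7* by 0.31 ± 0.06 (adjusted p = 0.0352). *Tox3* fell by 0.82 ± 0.15 (adjusted p = 0.0403), although its difference in experiment 2 was 0.02. *Penk* stood 1.53 lower without passing (adjusted p = 0.0622). In set 1, doxycycline removal against diet gave *Ogn* 0.21 ± 0.74, *Tox3* 0.03 ± 0.26 and *Penk* 0.36 ± 0.53. *Igfbp5* stood at −0.95 ± 0.46, and none passed (limma adjusted p 0.992 or higher). *Ogn*, *Tox3* and *Penk* thus lay about as low in set 1 with the transgene held off. *Lrrtm1* and *Rtn4r* passed in all 17 settings tried and without each of 18 arrays, and *Bcr* in 16 settings and without each array. Of the 18 fits without 1 array, *Ogn* passed in 14, *Zdhhc22* and *Zcchc7* in 9, *Igfbp5* in 8, and *Tcerg1l* and *Tox3* in 7. Of the 17 settings they passed in 16, 14, 10, 12, 9 and 10 in that order. The count of 9, from limma with 1471 genes at an unadjusted p under 0.05, was 187 without experiment 2 and 415 without the 2 arrays of highest actin ratio, alternatives chosen after seeing the data that kept all 9. It was 222 and 86 without monotransgenic replicates 1 and 2 of experiment 2, 316 without monotransgenic replicate 2 of set 3 and 16 without bitransgenic replicate 1 of experiment 2. It was 3 without removed replicate 1 of set 1 or without monotransgenic replicate 3 or bitransgenic replicate 1 or 3 of set 3. It was 4 without removed replicate 3 or monotransgenic replicate 1 or 3 of set 1 or monotransgenic replicate 1 of set 3, and 5 without bitransgenic replicate 3 of experiment 2.

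Cell type markers and the *Vipr2* segment, 4 lists in all, shifted downward over the 3 sets. All 17 oligodendrocyte and myelin markers were lower (median −0.19, camera adjusted p = 0.00207; adjusted p = 0.302 with an estimated correlation), *Ermn* (−0.85) and *Pdgfra* (−0.43) foremost, with 0 past the threshold over all genes or adjusted over the list alone. Without bitransgenic replicate 2 of experiment 2 the median was −0.12 (camera adjusted p = 0.00863). Of 16 dentate granule cell markers 13 were lower (median −0.17, camera adjusted p = 0.00172; adjusted p = 0.302 with an estimated correlation), none past the threshold over all genes, while *C1ql3* (−0.37), *C1ql2* (−1.24) and *Glis3* (−0.45) fell adjusted over the list alone. The list mean in monotransgenic replicates 1, 2 and 3 was 0.20, 0.06 and 0.22 in set 1, 0.00, −0.11 and 0.25 in experiment 2 and 0.25, −0.08 and 0.26 in set 3, and −0.32 to 0.08 in bitransgenic arrays. Of 6 meningeal and fibroblast markers 5 were lower (median −0.29, camera adjusted p = 0.0109; adjusted p = 0.302 with an estimated correlation), *Ogn* fell over all genes, and *Ogn* and *Lum* (−0.52) fell adjusted over the list alone. The mean of that list in the same replicates was 0.86, 0.42 and 0.52 in set 1, 0.18, −0.02 and 0.28 in experiment 2 and 0.81, −0.37 and 0.46 in set 3, and −0.49 to −0.01 in bitransgenic arrays. Without monotransgenic replicate 1 of experiment 2 that call was lost (camera adjusted p = 0.0862). The 4 genes of the *Vipr2* segment had a median of −0.28, with 0 past the threshold on either count (camera adjusted p = 0.0377; adjusted p = 0.302 with an estimated correlation). This call was lost without monotransgenic replicate 2 of set 1, monotransgenic replicate 1 or 3 or bitransgenic replicate 1 of experiment 2, or monotransgenic or bitransgenic replicate 3 of set 3, with adjusted p from 0.0662 to 0.17. Camera used a preset correlation of 0.01 between genes, and fry called none of these lists (adjusted p 0.103 or higher). In set 1 the dentate granule cell, oligodendrocyte and *Vipr2* lists were also called lower on the doxycycline diet, with the transgene held off. The meningeal list, not called there, had means of −0.41, −0.25 and −0.08 on the diet. After doxycycline removal against diet 0 lists were called lower. In set 1 these shifts are thus not shown to follow the transgene.

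No other list was called over the 3 sets. Median log2 differences and camera adjusted p were −0.15 (0.0774) for thalamus markers, −0.14 (0.0774) for inhibitory neuron markers, 0.08 (0.0774) for heat shock genes, 0.00 (0.385) for ATF4 and unfolded protein response genes, and −0.12 (0.423) for sex-linked marker genes. Circadian clock genes had −0.04 (0.423), activated microglia genes −0.03 (0.528), synaptic and plasticity genes −0.04 (0.528), neurogenesis and proliferation markers −0.12 (0.582) and p53 and DNA damage genes 0.04 (0.68). At an adjusted p of 0.784 stood astrocyte markers (−0.03), neocortex and striatum markers (0.02), microglia markers (−0.01), reactive astrocyte genes (−0.02) and immediate early genes (0.00). Oxidative phosphorylation genes (−0.01), antigen presentation genes (−0.04) and the NgR receptors, co-receptors and ligands (−0.12) stood at 0.861. CA1 markers (0.02) and endothelial and pericyte markers (−0.05) stood at 0.963, and interferon response genes (0.02), axon growth and regeneration genes (0.04) and choroid plexus markers (0.04) at 0.969. Glucocorticoid response genes (−0.06) stood at 0.975, and CA3, CA2 and hilar mossy cell markers (−0.02) at 0.982. Blood cell markers had 1 measured member and were not tested.

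**Figure D2:**
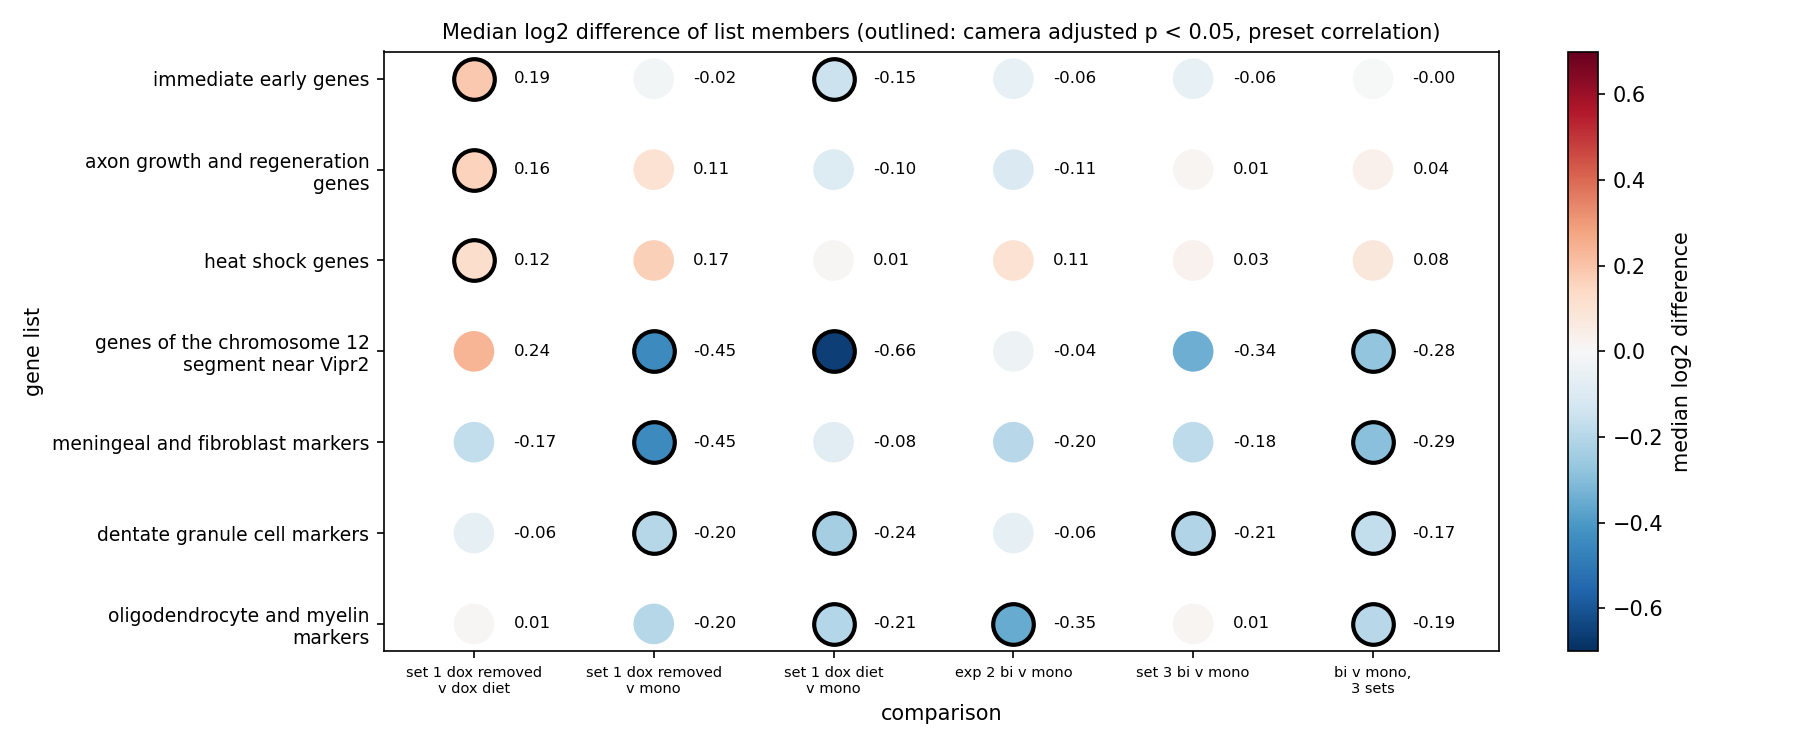
Median log2 difference (color and number) of the members of each called gene list (vertical axis) in the 6 comparisons (horizontal axis), with an outline where the camera adjusted p at the preset correlation was under 0.05. Dentate granule cell markers were called in 4 comparisons, and the *Vipr2* segment reached its lowest median, −0.66, on the doxycycline diet.

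No gene passed in the tests of a different response between sets. Tests of experiment 2 against another set could not tell doxycycline history from sex, read from *Xist* and *Eif2s3y*, or from RNA quality. Between experiment 2 and set 1 the lowest p belonged to *Gtpbp6* (difference of log2 differences −1.77), *Tox3* (1.73), *Btrc* (0.97), *Lum* (1.76) and *Plcb3* (−1.32), all at an adjusted p of 0.338. Between set 3 and set 1 they were *Tgm2* (1.35), *Tprn* (1.70), *Dsel* (−0.59), *Zmym2* (−0.79) and *Upk1b* (2.28), all at 1. Between set 3 and experiment 2 they were *Gtpbp6* (1.67), *Car3* (1.80), *4930432L08Rik* (1.32), *Scarb1* (0.99) and *Zc3h18* (1.04), all at 0.476. In limma 989, 438 and 1011 genes had an unadjusted p under 0.05 in the 3 tests, and 0 lists were called in each. The genes that passed in a single set are therefore not shown to be specific to it. For *Fst*, *Pmepa1* and *Klf10* the differences to set 1 in the step from monotransgenic to transgene-expressing mice had adjusted p from 0.338 to 1.

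Log2 differences across all 12499 genes correlated weakly between sets. Pearson r was 0.33 between set 1 after doxycycline removal and set 3, both against monotransgenic mice (permutation p = 0.05 of 400 within-set relabelings), 0.21 between set 1 and experiment 2 (permutation p = 0.06) and 0.08 between experiment 2 and set 3 (permutation p = 0.64). With set 1 taken as doxycycline removed against doxycycline diet, r was 0.15 to experiment 2 (permutation p = 0.08) and 0.26 to set 3 (permutation p = 0.05). The adjusted p over the 5 pairs was 0.1 or higher, with 0.01 the smallest unadjusted p possible. Without *Rtn4r* and *Lrrtm1* the r of set 1 with set 3 was 0.32. Spearman correlations ranked the pairs otherwise, with 0.13 for set 1 with set 3 (52.0% of genes with the same sign), 0.20 for set 1 with experiment 2 (57.9%) and −0.01 for experiment 2 with set 3 (49.5%).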

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

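The tests in this part that explain a pattern were chosen only after the pattern was seen, while the splits of the arrays were planned. With every probe set in the fit, 2 probe sets without a gene symbol responded differently in experiment 2. The first differed between experiment 2 and set 1 by −2.32 log2 units (limma adjusted p = 0.0108) and between set 3 and experiment 2 by 2.08 (adjusted p = 0.0354). The second differed by −2.11 (adjusted p = 0.0108) and 2.00 (adjusted p = 0.0354). In experiment 2 they fell by 2.16 and 2.11 log2 units, with log2 levels of 8.87 to 9.44 in the bitransgenic and 11.02 to 11.87 in the monotransgenic arrays. Among probe sets without a single gene symbol, which the comparisons by gene left out, 1 passed in set 1 after doxycycline removal against monotransgenic mice, 33 passed in experiment 2 and 3 passed over the 3 sets. No test of single outlying arrays was run in these groups of 3.

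The first pattern weighed is that *Ogn*, *Penk* (log2 6.77 to 7.05 against 8.91 to 9.29) and *Igfbp5* (7.83 to 9.09 against 9.78 to 10.57) were low in 3 of the 9 monotransgenic arrays, and *Tox3* less clearly so, with 6.87 in replicate 1 and 7.01 in replicate 3 of experiment 2. *Ogn* stood at log2 7.49 and 6.44 in experiment 2 replicates 1 and 2 and at 5.80 in set 3 replicate 2, against 9.10 to 9.73 in the other monotransgenic arrays and 4.58 to 7.25 in all bitransgenic arrays. In the same 3 arrays *Fst* was higher than in the other monotransgenic arrays (8.50 to 9.32 against 7.02 to 8.07). *Inhba* (8.56 to 8.83 against 6.92 to 7.77) and *Zdhhc22* (8.13 to 8.54 against 6.64 to 7.91) were higher there too. *Lrrtm1* was lower there (9.626 to 9.775 against 10.40 to 10.58), which widened its differences in experiment 2 and set 3. The label of a transgene-expressing mouse was argued against, since *Rtn4r* in these 3 arrays lay at least 1.06 log2 units under every transgene-expressing array of the same set, and RNA quality was argued against in set 3 by an actin 3' to 5' log2 ratio of 4.45, within the 4.17 to 4.63 of the other set 3 arrays, but stayed open in experiment 2, where the ratios were 5.97 and 4.90 against 4.84 to 6.45 in the other arrays of the set. As a hypothesis, these mice could carry tTA alone, since the labels of those sets do not say which transgene they carry and the insertion of a forebrain tTA line is known to lie in the *Vipr2* segment: its mean was −0.08, −0.25 and −0.0312 in these arrays, 0.33 to 0.47 in set 1 monotransgenic arrays, which lack tTA, and −0.44 to 0.20 in bitransgenic arrays. The 3 other monotransgenic arrays of those sets stood at 0.29, 0.24 and 0.43, above every bitransgenic array. Among monotransgenic arrays only the 3 of low *Ogn* thus lay within the bitransgenic range. The criterion chosen for this test, that no other monotransgenic array lie under set 1, decided nothing, because 2 of them did.

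The second pattern is *Lrrtm1*, on its brightest probe set at log2 11.25 or more in all 9 transgene-expressing arrays and at 10.63 or less in the other 12. On its other 2 probe sets the arrays overlapped. The lowest transgene-expressing and highest other arrays were at 6.84 and 7.68, and at 8.26 and 8.38. In set 1 *Lrrtm1* did not pass against the diet (limma adjusted p = 0.119) or monotransgenic mice (0.055). A probe set reading another RNA was argued against, since the lowest of the differences of its 3 probe sets over the 3 sets was 1.41. The insertion of the second transgene acting alone was argued against on the brightest probe set by a difference of 0.0905 ± 0.23 on the doxycycline diet. The other 2 probe sets stood at 0.48 ± 0.36 and 0.25 ± 0.40 there. They rose by 1.51 ± 0.36 and 0.75 ± 0.40 from diet to removal, the last by less than 2 standard errors. An insertion effect offset by the diet stayed open, because the diet and monotransgenic groups differed in genotype and doxycycline. Active tTA without NgR stayed open too, since doxycycline stops both. The difference of 1.11 log2 units after its removal could come from either. An insertion of the NgR transgene beside *Lrrtm1* stayed open. Its nearest measured neighbours were taken by order of gene start, so a gene that overlaps *Lrrtm1* was not told from a flanking one. The higher of them, *6330415B21Rik*, differed by 0.0784 ± 0.17 over the 3 sets. The other, *Ctnna2*, stood at −0.65 ± 0.18 and was lower in each set without passing (limma adjusted p = 0.112). An insertion can raise, lower or spare single neighbours. The biological reading, a response of *Lrrtm1* to NgR, rests on the same arrays and was not separated from these.

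The third pattern is *Fst*, *Inhba* and *Pmepa1* after doxycycline removal in set 1. *Fst* and *Inhba* were also high in the 3 monotransgenic arrays of low *Ogn*, so they were not high only where the transgene was on. On the doxycycline diet *Fst* stood −1.36 and *Pmepa1* −0.82 log2 units from the monotransgenic mice, so an effect of diet on these 2 genes could not be told from one of genotype. A diet effect acting alone on *Inhba* was argued against, since its difference there was −0.20 ± 0.39 against 2.08 after removal. A diet effect offset by genotype stayed open, because those groups differed in both. As a hypothesis, signalling by activin and TGF-beta might have changed: of 12 other measured genes of the pathway, chosen after values were seen, 6 stood higher and 6 lower, which leaves it open. Members stood apart from 0 in both directions, among them *Tgfbr1* (−0.81 ± 0.20), *Smad7* (0.49 ± 0.17) and *Skil* (0.40 ± 0.14), with none past the threshold over all genes (limma adjusted p 0.199 or higher).

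Splits of the same arrays gave a measure of what grouping alone produces. For 3 against 3 the 10 splits are too few for a share under 0.05. The real split gave 4 changed genes after doxycycline removal against diet (highest other 1, 1 of 10 splits as high), 9 against monotransgenic mice (highest other 0, 1 of 10), 3 on the diet (highest other 0, 1 of 10), 12 in experiment 2 (highest other 2245, 4 of 10) and 0 in set 3 (highest other 1, 10 of 10). For called lists the real and highest other counts were 3 and 4 (3 of 10 as high), 3 and 4 (4 of 10), 4 and 8 (3 of 10), 1 and 2 (3 of 10) and 1 and 5 (7 of 10) in the same order. Over the 3 sets 1 of 100 splits, the real one, gave as many as 9 genes (highest other 2), while 16 of 100 gave as many as 4 called lists (highest other 7). For the differences between sets the real count was 0 genes, which every split reaches. The 100 of 100 splits in each test therefore decide nothing, nor do the 10 of 10 for genes in set 3. The highest others were 1290 for experiment 2 against set 1, 153 for set 3 against set 1 and 902 for set 3 against experiment 2.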

How the results depend on the processing

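No result past its threshold reversed. *Rtn4r* over the 3 sets kept its call in every setting (1.91 to 2.46; leaving out each array in turn, 2.03 to 2.44). Counts of genes moved widely. Fits within sets keep each log2 difference and change only the estimate of its spread, so the moves under that setting came from the spread. The cause of the other moves was not tested. Counts follow in the order doxycycline removed against diet (4), removed against monotransgenic (9), diet against monotransgenic (3), experiment 2 (12), set 3 (0), the 3 sets (9), then experiment 2 against set 1 (0) and set 3 against experiment 2 (0), for those that moved by over 1.5 times. Fits within sets gave 85, 330, 32, 0, 1 and 4 for the first 6. Array weights gave 68, 254, 41, 890, 39, 1374, 75 and 52. A threshold of 0.1 gave 9, 28, 41, 2 and 128 (not moved: diet and differences between sets). No variance trend gave 2, 4, 1 and 5 (set 1 and the 3 sets). The Gapdh covariate gave 1, 5, 0, 77 and 16 (set 3 unmoved), and the *Xist* covariate 1 for diet and 4 for the 3 sets. A pseudocount of 1 gave 5 for removed against monotransgenic, and 64 gave 14 there and 5 in experiment 2. No filter gave 0 for diet and 2 in experiment 2, and the upper 40% gave 1 in experiment 2. In experiment 2 and over the 3 sets the deposited scale gave 40 and 54, the 75th percentile 27 and 49, all probe sets 84 and 19, and the mean of probe sets 19 and 5. All probe sets gave 1 for diet and 2 for each of the 2 differences between sets, and the mean of probe sets 5 for removed against monotransgenic and 1 for diet. Without set 3 the 3 sets gave 3. Alternatives chosen after seeing the data gave 187 without experiment 2, and, without the 2 arrays of highest actin ratio, 518 in experiment 2, 415 over the 3 sets, 26 for experiment 2 against set 1 and 135 for set 3 against experiment 2. Called lists, 16 in all, were 10 with no filter, 8 without those 2 arrays and 1 with an estimated correlation, and 16 with *Rtn4r* out of its own list.

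Leaving out each array in turn gave counts of 0 to 4, 0 to 6, 0 to 0, 5 to 646, 0 to 73 and 3 to 316 for the first 6, 0 to 5 for experiment 2 against set 1, 0 to 0 for set 3 against set 1, 0 to 8 for set 3 against experiment 2, and 11 to 20 called lists. The highest counts came without monotransgenic replicate 1 in experiment 2, and without monotransgenic replicate 2 of set 3 both in set 3 and over the 3 sets. Where an arm kept 2 arrays, the fit assumed that they vary like the other groups. Correlations past 0.05 before adjustment that were not so at first were, for set 1 (monotransgenic) with experiment 2, 0.28 with a pseudocount of 64, 0.17 with no filter, 0.28 in the upper 40%, and 0.25 on the deposited scale and at the 75th percentile; for set 1 with set 3, 0.25 with no filter. With set 1 taken against diet they were 0.20 on the deposited scale and at the 75th percentile for experiment 2, and 0.19 with no filter and 0.25 on the deposited scale and at the 75th percentile for set 3. Leaving out each array in turn gave r of 0.0816 to 0.25, 0.19 to 0.43 and −0.05 to 0.22 for set 1 with experiment 2, set 1 with set 3 and experiment 2 with set 3, the last changing sign without monotransgenic replicate 3 of experiment 2, and 0.06 to 0.18 and 0.16 to 0.32 for set 1 against diet with experiment 2 and set 3. In set 3, where 2 title prefixes are each shared by an array of both genotypes, a fit with the prefix as a factor gave 0 genes. In the other sets, no paired analysis was possible because the labels name no pairs.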

Other observations

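Hypotheses and their tests stand with the flagged results, and the values here were picked after the data were seen. *Zdhhc22*, *Bcr* and *Klf10* were traced through the sets because 1 or more comparisons called them. *Zdhhc22*, which rose over the 3 sets, stood 1.52, 0.86 and 1.16 log2 units higher in set 1, experiment 2 and set 3, and 0.81 ± 0.35 higher on the doxycycline diet (limma adjusted p = 1). *Bcr*, which fell over the 3 sets, stood at −0.85, −0.45 and −0.46 in the same order and at −0.41 ± 0.15 on the diet (adjusted p = 0.927). *Klf10* stood at 1.35, 0.01 and 0.53, and *Inhba* at 1.88, 0.15 and 0.81, with adjusted p of 0.338 and 0.479 for experiment 2 against set 1. *Klf10* also stood 0.57 ± 0.23 higher on the diet than in monotransgenic mice, without passing. From diet to removal it stood 0.78 ± 0.23 higher (limma adjusted p = 0.444). The monotransgenic arrays of low *Ogn* were high in *Inhba*, which narrowed its differences in experiment 2 and set 3. They stood at log2 8.56 and 8.83 against 7.60 in experiment 2, and at 8.61 against 6.92 and 7.23 in set 3. *Bcr* had 3 probe sets, with differences over the 3 sets of −0.59, −0.17 and 0.07, so its call rested on 1 of them. The same held over the 3 sets for *Igfbp5* (−1.48 and −0.15), *Tcerg1l* (−0.88 and 0.03) and *Zcchc7* (−0.31, −0.06 and 0.01), for *Pmepa1* after doxycycline removal (1.30, 0.06 and 0.40) and for *Dpp10* in set 1 against monotransgenic mice (−1.01 and −0.13). *Ceacam1* in experiment 2 had −1.08, 0.55 and −0.67 on the 3 probe sets kept, and *Septin6* on the diet had 1.34, 0.36, 1.08 and 0.26 on 4. *Ogn* had 2, at −2.61 and −0.92, and *Fst* had 2, at 2.37 and 2.20 after doxycycline removal. Probe sets under the filter followed weakly or not at all for *Upk1b* in set 1 against monotransgenic mice (−2.35 against −0.29, −0.62 and −0.45). In experiment 2 the same held for *Car3* (−1.53 against −0.15, −0.04 and −0.38) and *Habp2* (−1.10 against 0.22). It also held there for *Ubash3a* (−1.22 against −0.42) and *Pgap1* (1.16 against −0.25). Among axon growth genes over the 3 sets, the microtubule regulator gene *Stmn2* rose (0.48) and *Sox11* (−0.65) and *Ncam1* (−0.26) fell adjusted over the list alone (adjusted p = 0.0458 for each), with 0 past the threshold over all genes.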
